A study of Homo sapiens with 8 samples.

How the data were processed

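The labels describe C4-2B cells treated for 7 days, with ENZ at 10 uM and EPZ6438 at 1 uM as single agents. No separate doses are given for the combination. Total RNA was made into libraries with a NEBNext Ultra RNA kit and sequenced on an Illumina instrument, per the labels' protocols. Whether polyadenylated RNA was selected is not given in the sources used here. The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled to library size), with a column for each of the 8 libraries. STAR and the hg38 build were named in the submitters' processing notes, without versions. The counting tool, the gene annotation and any strand setting are not given in the sources used here, so antisense and overlapping genes were not named. Library columns were matched to samples by the short sample names in the labels, and groups and replicate numbers come from the sample titles.

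The table holds 26475 rows, of which 26443 carry values. 28 symbols had been turned into dates and were not named. 90.2% of symbols are in GENCODE release 29, which gave exonic lengths. FPKM hold no totals, so depth was read from the low values: where a gene has few fragments its FPKM are whole multiples of the value of 1 fragment. Relative to the first DMSO library, 79.7% to 87.3% of 801 to 1314 genes under 0.1 FPKM stood in such ratios within 0.04%. The absolute scale came from 780 genes with a single transcript, of which 58.3% lay within 5% of the median, so depths are estimates. A single fragment in a gene of 1 kilobase was worth 0.041 to 0.0648 FPKM, so a mean of 1 FPKM rests on few fragments in short genes. The deepest libraries were those of EPZ and the shallowest the first of DMSO and the second of Combination. Genes listed at 0 made up 37.4% of rows in the first DMSO library and 29% in the first Combination library.

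FPKM were used as deposited, on the log2(FPKM + 1) scale, for 11874 genes with a mean of at least 1 FPKM over all libraries. Fold changes on this scale understate the change of low genes. A linear model with the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with a moderated, two-sided test and an expression trend in the variance (5.47 prior and 4 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg for each of 6 comparisons, at a threshold of 0.05: each treatment against DMSO, Combination against each single agent, and the interaction (Combination minus ENZ minus EPZ plus DMSO). All groups share the estimate of spread because each has 2 libraries. Figures and depth used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

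Before the data were examined, 32 gene lists were fixed from general knowledge, of which 26 had at least 5 measured members. They were tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated per list. Camera sets a list against all other tested genes, so its p-values do not test a change from 0. With the estimated correlation no list passed in any of the 6 comparisons. The rule for named genes was fixed at the same time. It takes the 8 highest and 8 lowest log2 changes among genes past the threshold whose treated values both lie outside the control values for comparisons with DMSO, and the 5 highest and 5 lowest for the other comparisons, the interaction by adjusted p only. It adds up to 4 members of each list with the smallest p in comparisons with DMSO, and EZH2, KLK3, KLK2, TMPRSS2, FKBP5, MKI67, CDKN1A and CDKN1C in every group. Pseudogenes, small RNAs, clone-named and Y-linked genes were left out, and some genes from the end of a ranking were omitted for length. A few further genes that the rule takes are not reported here. Genes of near-identical families, such as kallikreins, HLA class I, metallothioneins and ribosomal protein genes with their pseudogenes, share reads and are uncertain.

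The fit was tested on simulated data with a seeded set of changed genes and, for each gene, the real spread averaged over the 4 groups. For 11874 simulated genes it recovered 88.1% of 1.5-fold and 94% of 2-fold changes for ENZ against DMSO, and 50.7% and 82.1% for the interaction. False calls made up 4.59% of calls for ENZ and 3.77% for the interaction. Only 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, far fewer than were called in the real comparisons. Real ENZ replicates differed by a median absolute log2 difference of 0.119, against 0.064 in DMSO, 0.0655 in EPZ and 0.074 in Combination. The simulated rates therefore need not hold for the real data, least of all for ENZ. The alternatives fixed in advance were a pseudocount of 0.1, no expression filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization (the last 2 for genes), only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn. Gene list tests under both scalings, and interaction values from ratios of mean FPKM with no pseudocount, were chosen after the data were seen.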

Results

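C4-2B cells, a castration-resistant prostate cancer line derived from LNCaP, were profiled by RNA sequencing after 7 days in DMSO, in ENZ at 10 uM, in EPZ6438 (EPZ) at 1 uM, or in both agents together (Combination). ENZ is the usual abbreviation of enzalutamide, an antiandrogen, and EPZ6438 is tazemetostat, an inhibitor of the histone methyltransferase EZH2. Each of the 4 groups had 2 libraries. Sequenced fragments, estimated from the steps between low FPKM values, came after rounding to about 15400000 and 20300000 in DMSO, 19300000 and 21800000 in ENZ, 24400000 and 22300000 in EPZ, and 19300000 and 16400000 in Combination. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Across 11874 tested genes, replicates correlated at r = 0.992 to 0.996, a correlation across genes, which are not independent replicates. The first principal component held 72.3% of the variance and the second 18.9%. On the first, both single-agent groups lay between DMSO and Combination, and on the second ENZ and EPZ lay on opposite sides. All levels below are mean FPKM ± SD (n = 2), and all changes are log2 fold changes on the log2(FPKM + 1) scale from limma, with Benjamini-Hochberg adjusted p-values. Among genes named in advance, KLK2 stood at 76.1 ± 5.76 in DMSO, 6.21 ± 0.342 in ENZ, 304 ± 6.15 in EPZ and 28.3 ± 1.7 in Combination. FKBP5 stood at 54.1 ± 0.561 in DMSO, 9.24 ± 0.778 in ENZ, 80.1 ± 3.51 in EPZ and 4.49 ± 0.291 in Combination. TMPRSS2 stood at 91.2 ± 1.51 in DMSO, 19.9 ± 0.244 in ENZ, 389 ± 10.7 in EPZ and 87.2 ± 1.6 in Combination. CDKN1A stood at 33.1 ± 0.904 in DMSO, 21.6 ± 1.4 in ENZ, 52.5 ± 0.783 in EPZ and 40.5 ± 1.51 in Combination.

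ENZ against DMSO asks what the antiandrogen changed. Androgen-induced genes fell: of 42 measured members 38 were lower and 3 higher, with a median of -1.46 (camera adjusted p = 1.79e-19, and adjusted p = 0.162 with an estimated correlation). KLK3, which encodes prostate-specific antigen, went from 996 ± 26.3 to 224 ± 1.24 FPKM, a change of -2.15 (SE 0.047). TMPRSS2, a serine protease gene, changed by -2.14 (SE 0.050) and FKBP5, a co-chaperone gene, by -2.43 (SE 0.071). KLK2 changed by -3.42 (SE 0.070), SLC45A3 by -3.44 (SE 0.074) and PMEPA1 by -2.8 (SE 0.057). KLK2 and KLK3 are similar in sequence, so their separate values are uncertain. Of 8 measured androgen-repressed genes 7 rose, with a median of 1.3 (camera adjusted p = 1.34e-05, and adjusted p = 0.256 with an estimated correlation), among them CAMK2N1 by 3.14 (SE 0.071), the scavenging chemokine receptor ACKR3 by 3.69 (SE 0.090) and FOLH1, prostate-specific membrane antigen, by 1.47 (SE 0.058). The members of the induced list that rose, named after their values were seen, were STEAP2 by 0.72 (SE 0.075), LIFR by 0.40 (SE 0.077) and TSC22D3 by 0.83 (SE 0.059).

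The highest change with ENZ among named genes was that of PLA2G2A, a secreted phospholipase gene, from 0.736 ± 0.242 to 99.6 ± 4.29 FPKM, or 5.86 (SE 0.12). COLEC12 rose by 3.42 (SE 0.064), the cholinesterase gene BCHE by 3.19 (SE 0.10) and LRRN1 by 3.18 (SE 0.077). LRRN1 was nearly silent in DMSO at 0.277 ± 0.00865 FPKM, and its change was 4.82 with a pseudocount of 0.1. Outside the androgen-induced and androgen-repressed lists, the lowest named were the sialyltransferase gene ST6GALNAC1 at -4.53 (SE 0.070), DPP4 at -3.31 (SE 0.064) and S100P at -3.12 (SE 0.15).

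Of 30 G2/M and mitosis genes 23 fell, with a median of -0.38 (camera adjusted p = 1.52e-05, and adjusted p = 0.29 with an estimated correlation), and of 32 G1/S and DNA replication genes 19 fell and 1 rose, with a median of -0.22 (camera adjusted p = 7.28e-04, and adjusted p = 0.283 with an estimated correlation). Of the G2/M genes 17 were lower and 1 higher after quantile normalization. PLK1, a mitotic kinase gene, changed by -0.97 (SE 0.064), CDC20, an activator of the anaphase-promoting complex, by -0.73 (SE 0.052), KIF20A by -0.84 (SE 0.073) and FEN1, a flap endonuclease gene, by -0.45 (SE 0.058). After quantile normalization the changes were CDC20 -0.47 and FEN1 -0.23. MKI67 stood at 33.1 ± 0.813 and 37.3 ± 1.84 FPKM and did not pass (0.17, adjusted p = 0.0929), although it did after quantile normalization (0.31, adjusted p = 0.0151). The 18 homologous recombination genes did not pass as a list (camera adjusted p = 0.497), with 4 higher and 1 lower, BARD1 among them at 0.87 (SE 0.071). All 16 ribosome biogenesis genes fell, with a median of -0.62 (camera adjusted p = 4.78e-08, and adjusted p = 0.162 with an estimated correlation), MYC at -0.81 (SE 0.053). Of 11 fatty acid synthesis genes 9 fell and 1 rose (camera adjusted p = 0.00166, and adjusted p = 0.272 with an estimated correlation), with the elongase genes ELOVL5 at -1.66 (SE 0.072) and ELOVL6 at 1.7 (SE 0.10) and FASN, the fatty acid synthase gene, at -1.2 (SE 0.084). Of 15 hypoxia and glycolysis genes 10 fell and 2 rose (camera adjusted p = 0.00213, and adjusted p = 0.283 with an estimated correlation), with hexokinase 2 (HK2) at -1.45 (SE 0.086). Of 7 antigen presentation genes 6 rose and none fell (camera adjusted p = 0.00147, and adjusted p = 0.283 with an estimated correlation), with TAPBP at 0.98 (SE 0.070) and HLA-B at 0.94 (SE 0.071), the latter a gene whose reads are shared with other class I genes. Developmental transcription factor genes bound by PRC2 were higher in 14 and lower in 4 of 28 (camera adjusted p = 0.0061, and adjusted p = 0.323 with an estimated correlation), and 15 of 23 cholesterol genes fell, with 3 higher (camera adjusted p = 0.00508, and adjusted p = 0.283 with an estimated correlation). The medians after quantile normalization were -0.13 for G1/S genes (2 higher and 7 lower, as deposited -0.22), -0.37 for ribosome biogenesis genes (0 higher and 13 lower, as deposited -0.62), -0.31 for fatty acid synthesis genes (2 higher and 7 lower, as deposited -0.48), -0.42 for hypoxia and glycolysis genes (1 higher and 10 lower, as deposited -0.63) and -0.22 for cholesterol genes (3 higher and 12 lower, as deposited -0.34). The camera calls of G1/S genes (adjusted p = 0.278), developmental transcription factor genes (adjusted p = 0.0743) and cholesterol genes (adjusted p = 0.0743) ended after quantile normalization.

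A further list that passed with ENZ was, higher, interferon response genes (7 higher and 1 lower of 13, camera adjusted p = 0.0342). It had an adjusted p = 0.283 with an estimated correlation. Lists that also passed, lower, were glucocorticoid-induced genes (2 higher and 6 lower of 9, camera adjusted p = 0.0238), housekeeping genes (1 higher and 8 lower of 12, camera adjusted p = 0.0168) and ribosomal protein genes (1 higher and 59 lower of 76, camera adjusted p = 1.82e-10). Their adjusted p-values were 0.283 for each, with an estimated correlation. No other list passed with ENZ. With quantile normalization the medians were -0.020 for housekeeping genes (2 higher and 4 lower, as deposited -0.22) and -0.057 for ribosomal protein genes (10 higher and 20 lower, as deposited -0.31). The camera calls of interferon response genes (adjusted p = 0.117), housekeeping genes (adjusted p = 0.771) and ribosomal protein genes (adjusted p = 0.425) ended after quantile normalization.

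In all, 6733 of 11874 genes changed with ENZ at adjusted p under 0.05, 3316 higher and 3417 lower, of which 303 rose and 168 fell at least 2-fold. The share of higher calls was 49.2%, against 47% after median-of-ratios scaling and 47.9% after quantile normalization. Those higher numbered 1980 at a mean of at least 5 FPKM; those at least 2-fold higher numbered 639 with a pseudocount of 0.1 and 178 at a mean of at least 5 FPKM. Both ENZ values lay outside both DMSO values for 77.1% of tested genes, against 33.3% by chance. EZH2 stood at 25.8 ± 0.551 and 24.8 ± 1.99 FPKM and did not pass (-0.054, adjusted p = 0.543), and CDKN1A, a cyclin-dependent kinase inhibitor gene, changed by -0.59 (SE 0.062). Genes given a change above passed unless stated, with the highest adjusted p at 0.00187, for LIFR. Adjusted over the list alone, the counts of the lists named here were the same, except 3 higher and 0 lower for homologous recombination repair, 3 higher and 10 lower for hypoxia and glycolysis, 1 higher and 60 lower for ribosomal protein genes.

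**Figure D1:**
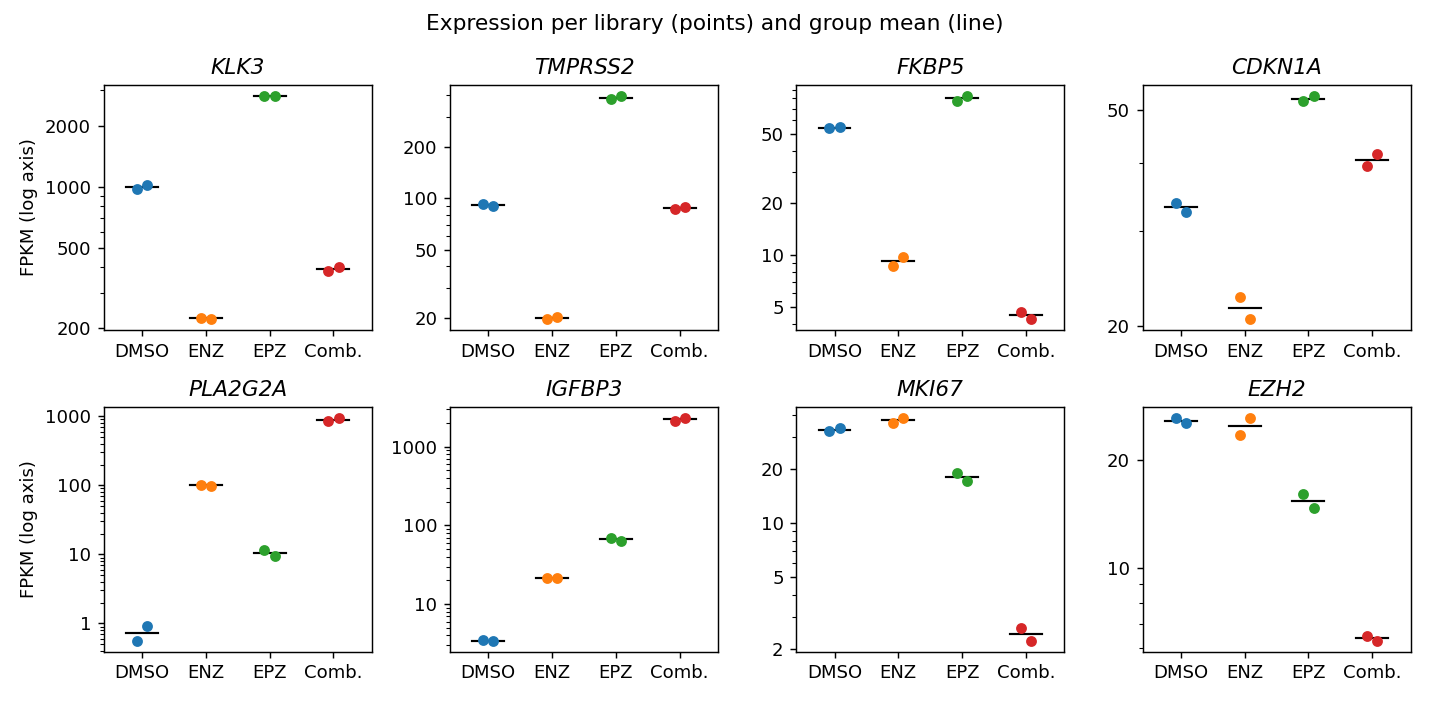
FPKM of 8 genes on log axes, each axis with its own range, for the 4 groups (Comb. is Combination); points are the 2 libraries of a group and the line is their mean. KLK3 lay at 996 FPKM in DMSO, 224 in ENZ, 2801 in EPZ and 392 in Combination, and MKI67 was lowest in Combination at 2.42.

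EPZ against DMSO asks what inhibiting EZH2 changed. Androgen-induced genes rose: 40 of 42 were higher and 1 lower, with a median of 0.86 (camera adjusted p = 5.47e-21, and adjusted p = 0.12 with an estimated correlation). KLK3 rose from 996 ± 26.3 to 2801 ± 1.5 FPKM, a change of 1.49 (SE 0.047), and TMPRSS2 from 91.2 ± 1.51 to 389 ± 10.7, a change of 2.08 (SE 0.050). NDRG1 changed by 3.09 (SE 0.069), the retinal dehydrogenase gene ALDH1A3 by 2.32 (SE 0.072) and FKBP5 by 0.56 (SE 0.071). The induced member that fell, named after its value was seen, was MPHOSPH9, at -0.63 (SE 0.065). Androgen-repressed genes went both ways, 3 higher and 5 lower of 8, and did not pass as a list (camera adjusted p = 0.644).

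Cell cycle genes fell with EPZ. All 32 G1/S and DNA replication genes were lower, with a median of -1.04 (camera adjusted p = 4.45e-17, and adjusted p = 0.108 with an estimated correlation), and all 30 G2/M and mitosis genes, with a median of -1.18 (camera adjusted p = 2.95e-16, and adjusted p = 0.18 with an estimated correlation). CDC45, a replicative helicase subunit gene, changed by -1.37 (SE 0.062), MCM2 by -1.21 (SE 0.056), CDC20 by -1.33 (SE 0.052), the mitotic kinase genes AURKB by -1.57 (SE 0.074) and PLK1 by -1.37 (SE 0.064), and cyclin A2 (CCNA2) by -1.51 (SE 0.087). MKI67 went from 33.1 ± 0.813 to 18 ± 1.25 FPKM, -0.84 (SE 0.078). All 18 homologous recombination genes fell, with a median of -0.90 (camera adjusted p = 1.37e-08, and adjusted p = 0.141 with an estimated correlation), BARD1 at -1.58 (SE 0.071) and EXO1 at -1.08 (SE 0.066). EZH2 fell from 25.8 ± 0.551 to 15.4 ± 0.945 FPKM, -0.71 (SE 0.072). The 12 PRC2 subunit genes did not pass as a list (camera adjusted p = 0.082), with 9 lower, such as RBBP7 at -0.70 (SE 0.056) and PHF19 at -1.04 (SE 0.093), and 2 higher, such as JARID2 at 0.86 (SE 0.079). CDKN1A changed by 0.65 (SE 0.062). CDKN1C, an EZH2-repressed inhibitor gene, lay under the expression filter at 0.405 ± 0.14 FPKM in DMSO, 0.602 ± 0.213 in ENZ, 1.11 ± 4.06e-04 in EPZ and 1.13 ± 0.151 in Combination, and was not tested.

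The highest changes with EPZ among named genes were those of IGFBP3, which encodes an insulin-like growth factor binding protein, from 3.45 ± 0.00259 to 66.7 ± 3.66 FPKM (3.93, SE 0.061), the pseudokinase gene TRIB2 (3.79, SE 0.063), CYP4F8 (3.49, SE 0.13), THBS1, thrombospondin 1 (3.4, SE 0.059), and PIP (3.2, SE 0.13). PIP was 5.3 with a pseudocount of 0.1. The lowest named was MT1F, a metallothionein gene, at -1.71 (SE 0.089), whose reads are shared with its close copies. Of 14 endoplasmic reticulum chaperone genes 13 rose and 1 fell, with a median of 0.66 (camera adjusted p = 6.79e-07, and adjusted p = 0.25 with an estimated correlation), among them HSPA5 at 0.79 (SE 0.058), which encodes the chaperone BiP, and XBP1 at 0.91 (SE 0.070). Glucocorticoid-induced genes were higher in 7 and lower in 2 of 9 (camera adjusted p = 0.00939, and adjusted p = 0.25 with an estimated correlation), SGK1 at 2.17 (SE 0.085) and TSC22D3 at 1.58 (SE 0.059), both also on the androgen-induced list. Of 7 antigen presentation genes 6 rose and none fell (camera adjusted p = 0.00124, and adjusted p = 0.275 with an estimated correlation), B2M by 0.77 (SE 0.063). Of 16 ribosome biogenesis genes 15 fell, with a median of -0.54 (camera adjusted p = 1.55e-06, and adjusted p = 0.141 with an estimated correlation). The 8 measured EZH2-repressed tumour genes did not pass (camera adjusted p = 0.431), with 3 higher, such as the receptor gene BMPR1B at 1.52 (SE 0.083), and 2 lower. The list holds 18 genes, and the rest lay under the expression filter. Genes silent in these cells therefore could not enter its test in any comparison. The 28 measured of 74 developmental transcription factor genes bound by PRC2 did not pass either (camera adjusted p = 0.879), with 7 higher, such as IRX3 at 0.86 (SE 0.082), and 8 lower, such as WT1 at -0.87 (SE 0.090). Their median was -0.078 and their mean -0.0014, against a median of -0.046 over all tested genes. Their test pointed up, and down after quantile normalization.

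Further lists that passed with EPZ were, higher, luminal marker genes (7 higher and 2 lower of 11, camera adjusted p = 0.00533), mesenchymal marker genes (3 higher and 1 lower of 6, camera adjusted p = 0.0418) and immediate early genes (5 higher and 2 lower of 8, camera adjusted p = 0.0375). Adjusted p-values with an estimated correlation were 0.275, 0.25 and 0.445, in that order. Lists that also passed, lower, were housekeeping genes (0 higher and 10 lower of 12, camera adjusted p = 0.0125) and ribosomal protein genes (2 higher and 35 lower of 76, camera adjusted p = 0.00431). With an estimated correlation the adjusted p-values were 0.275 and 0.616, in that order. No other list passed with EPZ. The median after median-of-ratios scaling was -0.10 for ribosomal protein genes (2 higher and 22 lower, as deposited -0.15). The camera call of mesenchymal marker genes (adjusted p = 0.0541) ended after median-of-ratios scaling. With quantile normalization the medians were -0.13 for housekeeping genes (1 higher and 6 lower, as deposited -0.26) and -0.035 for ribosomal protein genes (7 higher and 14 lower, as deposited -0.15). The camera calls of mesenchymal marker genes (adjusted p = 0.0659), housekeeping genes (adjusted p = 0.0659) and ribosomal protein genes (adjusted p = 0.455) ended after quantile normalization.

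In all, 6623 genes changed with EPZ, 2775 higher and 3848 lower, of which 220 rose and 190 fell at least 2-fold. The share of higher calls was 41.9%, against 49.4% after median-of-ratios scaling and 47.7% after quantile normalization. Those higher numbered 1819 at a mean of at least 5 FPKM; those at least 2-fold higher numbered 476 with a pseudocount of 0.1 and 145 at a mean of at least 5 FPKM; those at least 2-fold lower numbered 290 with a pseudocount of 0.1 and 111 after quantile normalization. Both EPZ values lay outside both DMSO values for 82.2% of tested genes, against 33.3% by chance. Of genes higher with both single agents there were 1593, against 775 for independent lists, and of genes lower with both 2086, against 1107. Genes lower with ENZ and higher with EPZ numbered 356, against 799. Genes named with EPZ passed, with the highest adjusted p at 1.60e-04, for FKBP5. Adjusted over the list alone, the counts of the lists named here were the same, except 6 higher and 8 lower for developmental transcription factor genes bound by PRC2, 8 higher and 2 lower for luminal prostate markers, 1 higher and 30 lower for ribosomal protein genes. The changes with ENZ and EPZ correlated across genes at r = 0.376. Unchanged groups against the same DMSO libraries gave 0.503 in 100 simulated draws. That value is fixed by construction whatever the data, so it is no reference for r. The covariance of the changes with ENZ and EPZ was 0.0798, against 0.00749 simulated, so the spread between the DMSO libraries gave a small part of it. A shift common to both DMSO libraries would not show in that spread. Part of these overlaps may still come from the shared DMSO libraries, which are too few to split.

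Combination against DMSO asks what both agents did together. Cell cycle genes fell: all 32 G1/S and DNA replication genes, with a median of -2.78 (camera adjusted p = 4.74e-12, and adjusted p = 0.206 with an estimated correlation), and all 30 G2/M and mitosis genes, with a median of -3.29 (camera adjusted p = 4.74e-12, and adjusted p = 0.262 with an estimated correlation). RRM2, a ribonucleotide reductase subunit gene, changed by -4.51 (SE 0.065), the transcription factor gene MYBL2 by -4.38 (SE 0.064), the mitotic kinase genes AURKB by -4.3 (SE 0.074) and PLK1 by -4.07 (SE 0.064), CDC20 by -4.06 (SE 0.052) and BIRC5, survivin, by -4.02 (SE 0.066). MKI67 fell from 33.1 ± 0.813 to 2.42 ± 0.282 FPKM (-3.32, SE 0.078) and EZH2 from 25.8 ± 0.551 to 6.38 ± 0.138 (-1.86, SE 0.072). All 18 homologous recombination genes fell, with a median of -1.67 (camera adjusted p = 7.03e-06, and adjusted p = 0.262 with an estimated correlation), the exonuclease gene EXO1 at -3.21 (SE 0.066) and FANCI at -2.61 (SE 0.066).

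**Figure D2:**
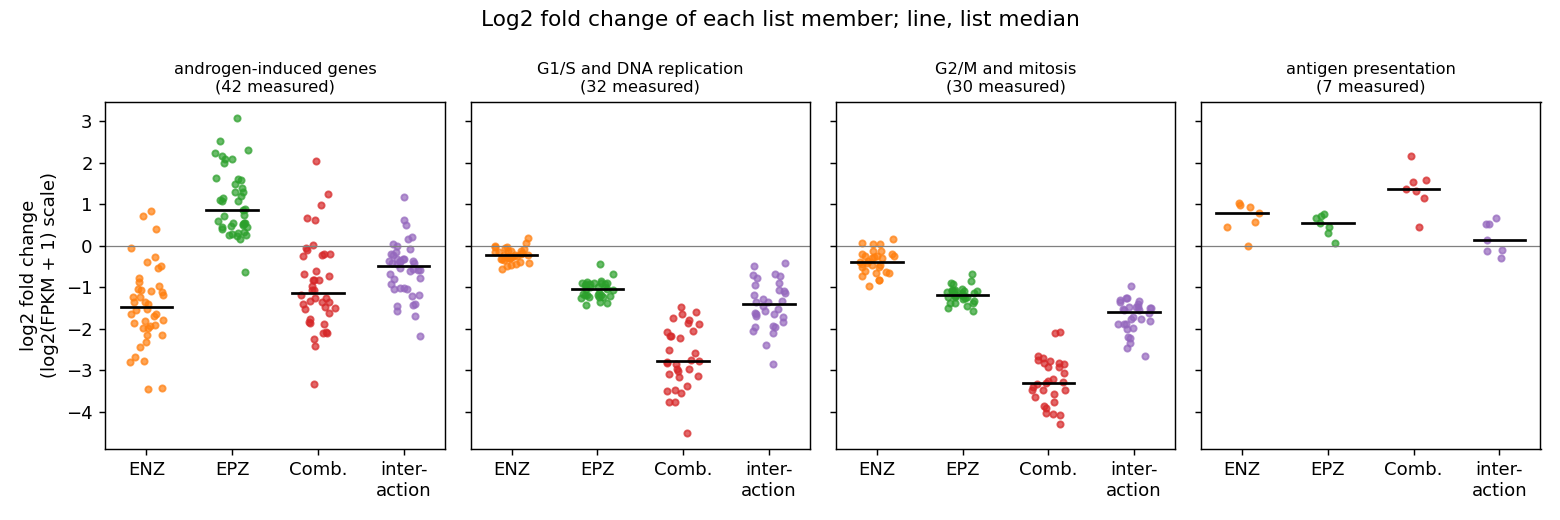
Log2 fold changes on the log2(FPKM + 1) scale of the measured members of 4 gene lists for ENZ, EPZ and Combination (Comb.) against DMSO and for the interaction, the departure of Combination from the sum of both single-agent changes. Each point is a gene and each line a list median: androgen-induced genes had medians of -1.46, 0.86 and -1.13 with ENZ, EPZ and Combination, and G2/M and mitosis genes -0.38, -1.18 and -3.29.

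Androgen-induced genes were mostly lower in Combination, 33 of 42, with 5 higher and a median of -1.13 (camera adjusted p = 1.78e-04, and adjusted p = 0.262 with an estimated correlation). FKBP5 changed by -3.33 (SE 0.071) and CENPN by -2.41 (SE 0.069). Those that rose, named after their values were seen, were TSC22D3 by 2.05 (SE 0.059), NDRG1 by 1.26 (SE 0.069), TMEM79 by 0.98 (SE 0.080), STEAP2 by 0.66 (SE 0.075) and LIFR by 0.61 (SE 0.077). KLK3 stood at 392 ± 12.2 FPKM, -1.35 (SE 0.047) against DMSO, a change of -0.51 after quantile normalization. TMPRSS2 stood at 91.2 ± 1.51 FPKM in DMSO and 87.2 ± 1.6 in Combination and did not pass (-0.063, adjusted p = 0.267), though it was higher, and passed, by 0.11 after median-of-ratios scaling and 0.62 after quantile normalization. KLK2 changed by -1.39 (SE 0.070). After quantile normalization the changes were KLK2 -0.83 and STEAP2 1.29. Of 8 androgen-repressed genes 5 rose and 1 fell (camera adjusted p = 0.0116, and adjusted p = 0.262 with an estimated correlation), CAMK2N1 by 3.44 (SE 0.071) and ACKR3 by 2.86 (SE 0.090). CDKN1A rose by 0.28 (SE 0.062), or 0.46 after median-of-ratios scaling and 0.84 after quantile normalization. The median after quantile normalization was 0.92 for androgen-repressed genes (5 higher and 1 lower, as deposited 0.48). The camera call of androgen-repressed genes (adjusted p = 0.059) ended after quantile normalization.

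The highest changes in Combination among named genes were those of PLA2G2A, from 0.736 ± 0.242 to 896 ± 73.9 FPKM (9.02, SE 0.12), and IGFBP3, from 3.45 ± 0.00259 to 2242 ± 126 (8.98, SE 0.061). LRRN1 changed by 6.36 (SE 0.077), COLCA1 by 4.75 (SE 0.090), the syndecan gene SDC2 by 4.6 (SE 0.073) and TRIB2 by 4.6 (SE 0.063). All 7 measured antigen presentation genes rose, with a median of 1.38 (camera adjusted p = 2.68e-04, and adjusted p = 0.262 with an estimated correlation), HLA-B by 2.17 (SE 0.071), HLA-C by 1.55 (SE 0.079) and TAPBP, tapasin, by 1.32 (SE 0.070). Of 6 Wnt pathway genes 5 rose and 1 fell (camera adjusted p = 0.0116, and adjusted p = 0.262 with an estimated correlation), WNT5A by 3.65 (SE 0.088) and LEF1 by 2.03 (SE 0.085). Of 28 developmental transcription factor genes 19 rose and 6 fell, with a median of 0.67 (camera adjusted p = 0.00109, and adjusted p = 0.262 with an estimated correlation), HOXC4 by 2.34 (SE 0.092) and HOXC13 by 1.65 (SE 0.081). Of 6 mesenchymal markers 4 were higher and 2 lower, which did not pass as a list (camera adjusted p = 0.0837), with fibronectin (FN1) at 2.23 (SE 0.064) and the collagen gene COL1A1 at 1.78 (SE 0.10).

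In Combination all 16 ribosome biogenesis genes fell, with a median of -1.89 (camera adjusted p = 1.78e-06, and adjusted p = 0.246 with an estimated correlation), the nucleolar genes FBL at -2.38 (SE 0.059), NCL at -2.05 (SE 0.054) and NOLC1 at -1.93 (SE 0.052), and MYC at -1.98 (SE 0.053). Of 76 ribosomal protein genes 74 fell, with a median of -1.07 (camera adjusted p = 2.04e-12, and adjusted p = 0.262 with an estimated correlation), RPL14 at -1.57 (SE 0.051), although these genes share reads with many pseudogenes. Of 11 fatty acid synthesis genes 10 fell and 1 rose (camera adjusted p = 0.00165, and adjusted p = 0.262 with an estimated correlation), the desaturase genes SCD at -2.7 (SE 0.058) and FADS1 at -2.6 (SE 0.059). Of 23 cholesterol genes 18 fell and 2 rose (camera adjusted p = 0.0043, and adjusted p = 0.262 with an estimated correlation), INSIG1 at -1.99 (SE 0.050). Of 15 hypoxia and glycolysis genes 11 fell and 2 rose (camera adjusted p = 0.049, and adjusted p = 0.306 with an estimated correlation), lactate dehydrogenase A (LDHA) at -2.96 (SE 0.064). The call of that list ended with the replicate number as a block (adjusted p = 0.0533). Of 12 housekeeping genes 10 fell, with a median of -0.97 (camera adjusted p = 0.00569, and adjusted p = 0.262 with an estimated correlation), TFRC at -2.19 (SE 0.056) and GAPDH at -1.73 (SE 0.055). After quantile normalization the changes were NCL -1.33, RPL14 -0.84 and GAPDH -0.93. Median-of-ratios scaling shifted the changes of all genes against DMSO by a median of 0.16 in Combination, 0.050 in EPZ and -0.013 in ENZ. With that scaling the Combination medians were -0.91 for ribosomal protein genes, -0.79 for housekeeping genes, -3.14 for G2/M and mitosis genes and -0.98 for androgen-induced genes. With quantile normalization the medians were -0.39 for ribosomal protein genes (2 higher and 59 lower, as deposited -1.07), -0.92 for fatty acid synthesis genes (0 higher and 9 lower, as deposited -1.55), -0.51 for cholesterol genes (3 higher and 18 lower, as deposited -0.81) and -0.40 for housekeeping genes (4 higher and 8 lower, as deposited -0.97). The camera call of housekeeping genes (adjusted p = 0.154) ended after quantile normalization.

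The remaining lists did not pass in Combination. These were luminal prostate markers (4 higher and 7 lower of 11, camera adjusted p = 0.446), PRC2 subunits (3 and 8 of 12, 0.35), EZH2-repressed tumour genes (3 and 4 of 8, 0.881), p53 targets (10 and 8 of 21, 0.177) and interferon response genes (7 and 5 of 13, 0.273). Among them were also integrated stress response (7 and 6 of 14, 0.551), steroid synthesis and inactivation (1 and 5 of 7, 0.35), glucocorticoid-induced (3 and 4 of 9, 0.881), immediate early (4 and 2 of 8, 0.273) and germline genes (0 and 5 of 6, 0.0675). The 14 endoplasmic reticulum chaperone genes, 3 higher and 8 lower with a median of -0.31, did not pass either (camera adjusted p = 0.571), but did after quantile normalization, with a median of 0.31 (camera adjusted p = 0.0431). EZH2-repressed genes had a median of -0.28 and a mean of -0.072, against a median of -0.15 over all tested genes, and their test pointed up. The integrated stress response had a median of 0.17 and a mean of -0.060. Markers of other cell types were scarce: neuroendocrine markers had 4 of 20 members over the filter, basal epithelial 4 of 13, fibroblast 2 of 10, leukocyte 2 of 10 and endothelial 0 of 8. The highest single value among them was 15.2 FPKM, in the basal list. No mitochondrially encoded gene was among the rows used.

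In all, 9591 of 11874 genes changed in Combination, 3957 higher and 5634 lower, of which 1212 rose and 1898 fell at least 2-fold. The share of higher calls was 41.3%, against 50.0% after median-of-ratios scaling and 48.2% after quantile normalization. Those higher numbered 6633 with no filter and 2147 at a mean of at least 5 FPKM; those at least 2-fold higher numbered 578 at a mean of at least 5 FPKM; those at least 2-fold lower numbered 1251 after quantile normalization. Both values lay outside both DMSO values for 90.9% of tested genes, against 33.3% by chance. Genes given a change passed unless stated, with the highest adjusted p at 0.00188, for CDKN1A. Adjusted over the list alone, the counts of the lists named here were the same. The FPKM sum per library was 318599 and 314611 in DMSO, 283211 and 276531 in ENZ, 288954 and 296532 in EPZ, and 218646 and 224223 in Combination.

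Combination against ENZ asks what EPZ added to ENZ. Cell cycle genes were lower, all 32 of G1/S and DNA replication with a median of -2.56 (camera adjusted p = 7.91e-15, and adjusted p = 0.135 with an estimated correlation) and all 30 of G2/M and mitosis with a median of -2.83 (camera adjusted p = 9.92e-15, and adjusted p = 0.198 with an estimated correlation), RRM2 at -4.09 (SE 0.065), MYBL2 at -3.85 (SE 0.064) and AURKB at -3.8 (SE 0.074). Androgen-induced genes were higher in 25 and lower in 9 of 42, with a median of 0.37 (camera adjusted p = 5.64e-06, and adjusted p = 0.198 with an estimated correlation). KLK3 was higher by 0.80 (SE 0.047) and TMPRSS2 by 2.08 (SE 0.050), while FKBP5 was lower at -0.90 (SE 0.071). The change of KLK3 was 1.26 after quantile normalization. IGFBP3 was the highest named, at 6.64 (SE 0.061), with COLCA1 at 4.81 (SE 0.090) and TRIB2 at 3.75 (SE 0.063). In all, 8403 genes differed, 3001 higher and 5402 lower (at least 2-fold, 427 and 967), so that 35.7% were higher, against 51.2% after median-of-ratios scaling and 51% after quantile normalization. Those higher numbered 4956 with no filter and 1676 at a mean of at least 5 FPKM; those at least 2-fold higher numbered 689 with a pseudocount of 0.1, 200 at a mean of at least 5 FPKM, 641 after median-of-ratios scaling and 689 after quantile normalization. The median shift from median-of-ratios scaling was 0.17. The named genes passed, with the highest adjusted p at 2.51e-06, for FKBP5.

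Further lists that passed against ENZ were, higher, developmental transcription factor genes (14 higher and 7 lower of 28, camera adjusted p = 0.0040), mesenchymal marker genes (5 higher and 1 lower of 6, camera adjusted p = 0.0165), antigen presentation genes (7 higher and 0 lower of 7, camera adjusted p = 2.42e-04) and glucocorticoid-induced genes (6 higher and 3 lower of 9, camera adjusted p = 0.0428). Their adjusted p-values were 0.272, 0.198, 0.198 and 0.252, in that order, with an estimated correlation. Also passing in that direction were Wnt pathway genes (5 higher and 1 lower of 6, camera adjusted p = 0.00589) and immediate early genes (6 higher and 0 lower of 8, camera adjusted p = 0.00628). Adjusted p-values with an estimated correlation were 0.198 and 0.252, in that order. Lists that also passed, lower, were homologous recombination genes (0 higher and 18 lower of 18, camera adjusted p = 4.66e-08), cholesterol genes (2 higher and 17 lower of 23, camera adjusted p = 0.00857), fatty acid synthesis genes (0 higher and 10 lower of 11, camera adjusted p = 0.00264) and ribosome biogenesis genes (0 higher and 16 lower of 16, camera adjusted p = 1.08e-06). With an estimated correlation the adjusted p-values were 0.198, 0.271, 0.198 and 0.198, in that order. Also passing in that direction were germline genes (0 higher and 5 lower of 6, camera adjusted p = 0.0259), housekeeping genes (0 higher and 10 lower of 12, camera adjusted p = 0.00589) and ribosomal protein genes (0 higher and 74 lower of 76, camera adjusted p = 3.83e-13). Their adjusted p-values were 0.252, 0.208 and 0.198, in that order, with an estimated correlation. No other list passed against ENZ, except luminal marker genes after quantile normalization (camera adjusted p = 0.00472). The medians after median-of-ratios scaling were 0.41 for developmental transcription factor genes (19 higher and 5 lower, as deposited 0.24) and -0.33 for cholesterol genes (2 higher and 14 lower, as deposited -0.51). The camera call of glucocorticoid-induced genes (adjusted p = 0.126) ended after median-of-ratios scaling. With quantile normalization the medians were 0.40 for developmental transcription factor genes (17 higher and 7 lower, as deposited 0.24), 0.82 for mesenchymal marker genes (4 higher and 1 lower, as deposited 0.54), -0.33 for cholesterol genes (3 higher and 14 lower, as deposited -0.51), -0.54 for fatty acid synthesis genes (1 higher and 8 lower, as deposited -0.93), 0.74 for immediate early genes (6 higher and 0 lower, as deposited 0.47), -0.39 for germline genes (0 higher and 5 lower, as deposited -0.63), -0.38 for housekeeping genes (3 higher and 7 lower, as deposited -0.79) and -0.33 for ribosomal protein genes (0 higher and 64 lower, as deposited -0.77). The camera calls of mesenchymal marker genes (adjusted p = 0.0637), glucocorticoid-induced genes (adjusted p = 0.137) and housekeeping genes (adjusted p = 0.0557) ended after quantile normalization. Adjusted over the list alone, the counts of the lists named here were the same, except 25 higher and 10 lower for androgen-induced genes, 0 higher and 6 lower for germline and cancer-testis genes.

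Combination against EPZ asks what ENZ added to EPZ. Androgen-induced genes were lower in 39 and higher in 1 of 42, with a median of -2.12 (camera adjusted p = 2.30e-13, and adjusted p = 0.179 with an estimated correlation), FKBP5 at -3.89 (SE 0.071), SLC45A3 at -3.86 (SE 0.074), KLK3 at -2.84 (SE 0.047) and TMPRSS2 at -2.14 (SE 0.050). SLC43A1, an amino acid transporter gene, was lower at -3.69 (SE 0.055) and the pepsinogen gene PGC at -3.6 (SE 0.10). Androgen-repressed genes were higher in 7 of 8 (camera adjusted p = 1.46e-04, and adjusted p = 0.188 with an estimated correlation). All 32 G1/S genes, with a median of -1.66 (camera adjusted p = 3.54e-12, and adjusted p = 0.179 with an estimated correlation), and all 30 G2/M genes, with a median of -2.09 (camera adjusted p = 1.58e-12, and adjusted p = 0.188 with an estimated correlation), were lower. All 14 endoplasmic reticulum chaperone genes were lower, with a median of -0.73 (camera adjusted p = 2.91e-04, and adjusted p = 0.222 with an estimated correlation). PLA2G2A was the highest named, at 6.29 (SE 0.12), followed by LRRN1 at 5.6 (SE 0.077) and IGFBP3 at 5.05 (SE 0.061). CDKN1A was lower at -0.37 (SE 0.062), but 0.082 and not past the threshold (adjusted p = 0.213) after quantile normalization. In all, 8650 genes differed, 3463 higher and 5187 lower (at least 2-fold, 634 and 1051), with a median shift of 0.11 under median-of-ratios scaling. After median-of-ratios scaling 4242 were higher and 4428 lower, and after quantile normalization 4113 and 4309. Those higher numbered 5480 with no filter and 1857 at a mean of at least 5 FPKM; those at least 2-fold higher numbered 962 with a pseudocount of 0.1 and 284 at a mean of at least 5 FPKM. The named genes passed, with the highest adjusted p at 4.27e-04, for CDKN1A. The median after quantile normalization was -0.39 for endoplasmic reticulum chaperone genes (1 higher and 9 lower, as deposited -0.73).

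Further lists that passed against EPZ were, higher, developmental transcription factor genes (18 higher and 6 lower of 28, camera adjusted p = 1.29e-04), antigen presentation genes (6 higher and 1 lower of 7, camera adjusted p = 0.00169) and Wnt pathway genes (5 higher and 0 lower of 6, camera adjusted p = 0.00312). Adjusted p-values with an estimated correlation were 0.193, 0.195 and 0.188, in that order. Lists that also passed, lower, were homologous recombination genes (1 higher and 16 lower of 18, camera adjusted p = 1.83e-04), cholesterol genes (2 higher and 19 lower of 23, camera adjusted p = 8.95e-04), fatty acid synthesis genes (1 higher and 9 lower of 11, camera adjusted p = 3.34e-04) and hypoxia and glycolysis genes (1 higher and 12 lower of 15, camera adjusted p = 0.00109). With an estimated correlation the adjusted p-values were 0.188, 0.193, 0.188 and 0.188, in that order. Also passing in that direction were ribosome biogenesis genes (0 higher and 16 lower of 16, camera adjusted p = 5.91e-07), germline genes (0 higher and 5 lower of 6, camera adjusted p = 0.0131), housekeeping genes (1 higher and 10 lower of 12, camera adjusted p = 0.00994) and ribosomal protein genes (0 higher and 74 lower of 76, camera adjusted p = 6.02e-15). Their adjusted p-values were 0.179, 0.195, 0.195 and 0.188, in that order, with an estimated correlation. No other list passed against EPZ. With quantile normalization the medians were -0.80 for hypoxia and glycolysis genes (1 higher and 12 lower, as deposited -1.34), -0.22 for housekeeping genes (4 higher and 6 lower, as deposited -0.74) and -0.36 for ribosomal protein genes (1 higher and 61 lower, as deposited -0.97). The camera call of housekeeping genes (adjusted p = 0.313) ended after quantile normalization. Adjusted over the list alone, the counts of the lists named here were the same, except 1 higher and 13 lower for hypoxia and glycolysis.

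The effect of each agent was then set against its effect in the presence of the other, in comparisons that share no library. This presumes the same doses in Combination as alone, which the labels do not give. Across genes, which are not independent replicates, changes with ENZ alone and with ENZ added to EPZ correlated at r = 0.778 (rho = 0.793). For EPZ alone and EPZ added to ENZ the values were r = 0.745 (rho = 0.747). ENZ raised 2407 genes in both settings, against 967 for independent lists, and lowered 3096, against 1493. EPZ raised 1849 in both, against 701, and lowered 3356, against 1751. The SD of the changes across genes was 0.476 for ENZ alone and 0.726 with EPZ present, and 0.447 for EPZ alone and 0.69 with ENZ present.

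**Figure D3:**
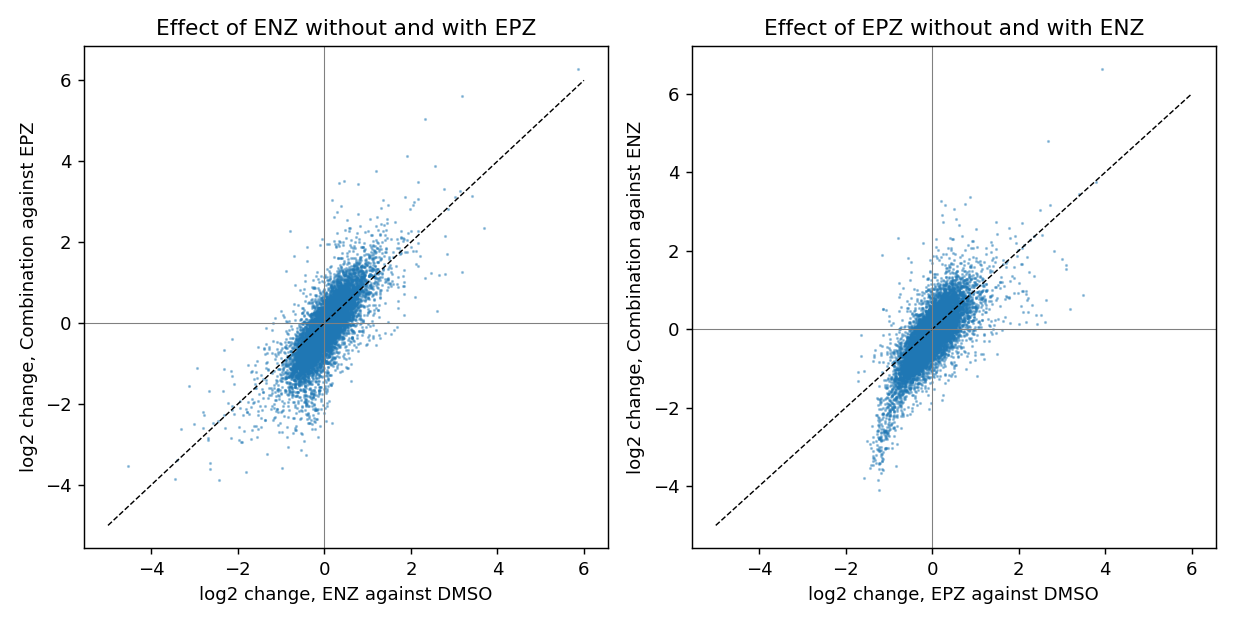
Log2 fold changes on the log2(FPKM + 1) scale of each agent alone (x axis) and in the presence of the other (y axis), with 1 point per tested gene and a dashed line where both are equal. The correlations across genes are r = 0.778 for ENZ and r = 0.745 for EPZ, and a group of genes lowered by EPZ lies below the line.

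The interaction tests, gene by gene, whether Combination departed from the sum of both single-agent log2 changes. The labels give no doses for Combination, so that sum has meaning only if the single-agent doses were used. Cell cycle genes lay below that sum, all 32 G1/S genes with a median of -1.4 (camera adjusted p = 3.27e-19, and adjusted p = 0.0863 with an estimated correlation) and all 30 G2/M genes with a median of -1.59 (camera adjusted p = 1.22e-19, and adjusted p = 0.133 with an estimated correlation), RRM2 at -2.86 (SE 0.092), MKI67 at -2.65 (SE 0.11) and MYBL2 at -2.61 (SE 0.090). Also below it were 15 of 18 homologous recombination genes (camera adjusted p = 2.38e-07, and adjusted p = 0.133 with an estimated correlation), 70 of 76 ribosomal protein genes (camera adjusted p = 1.60e-17, and adjusted p = 0.176 with an estimated correlation), 12 of 14 endoplasmic reticulum chaperone genes (camera adjusted p = 1.23e-05, and adjusted p = 0.204 with an estimated correlation) and 10 of 11 fatty acid synthesis genes (camera adjusted p = 2.68e-06, and adjusted p = 0.133 with an estimated correlation). BARD1, on the homologous recombination list, lay above the sum at 0.52 (SE 0.10). Of 42 androgen-induced genes 28 lay below and 3 above (camera adjusted p = 2.82e-05, and adjusted p = 0.204 with an estimated correlation). Departures of genes nearly silent in a group depend on the pseudocount. PIP, listed at 0 in 1 ENZ library, lay at -2.68 (SE 0.18), or -2.33 as a ratio of mean FPKM with no pseudocount, an alternative chosen after the data were seen. CYP4F8 lay at -2.61 (SE 0.18), or -1.58 with a pseudocount of 0.1 and -0.45 with none. Above the sum were ZFP36L2, an RNA-binding protein gene, at 3.12 (SE 0.080), the kinase gene DAPK1 at 2.87 (SE 0.14) and IGFBP3 at 2.71 (SE 0.086). Tenascin C (TNC) lay at 3.06 (SE 0.13) and the uroplakin gene UPK1A at 2.67 (SE 0.15), but at 0.62 and 0.92 with no pseudocount. TMPRSS2 (0.00041, adjusted p = 0.997) and KLK2 (0.036, adjusted p = 0.801) did not pass, nor did CDKN1A (0.23, adjusted p = 0.0664). After quantile normalization they passed, at 0.34, 0.31 and 0.54, and CDKN1A also passed after median-of-ratios scaling (0.36) and without the first ENZ library (0.29). KLK3 lay below the sum at -0.69 (SE 0.067), or -0.21 after quantile normalization. In all, 4703 genes departed, 1186 above and 3517 below, so that 25.2% lay above, against 44.3% after median-of-ratios scaling and 49.3% after quantile normalization. Those above numbered 711 at a mean of at least 5 FPKM, 1958 after median-of-ratios scaling, 2454 after quantile normalization and 777 without the second EPZ library. The highest adjusted p among named genes that passed was 0.00307, for BARD1. The median shift from median-of-ratios scaling was 0.12. The medians after quantile normalization were -0.32 for ribosomal protein genes (1 above and 52 below, as deposited -0.63), -0.47 for endoplasmic reticulum chaperone genes (0 above and 9 below, as deposited -0.76) and -0.33 for androgen-induced genes (7 above and 24 below, as deposited -0.50).

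Further lists that passed in the interaction were, above the sum, developmental transcription factor genes (10 above and 3 below of 28, camera adjusted p = 1.70e-04), p53 target genes (6 above and 3 below of 21, camera adjusted p = 0.00516) and Wnt pathway genes (3 above and 1 below of 6, camera adjusted p = 0.00136). Adjusted p-values with an estimated correlation were 0.204, 0.133 and 0.164, in that order. Lists that also passed, below it, were cholesterol genes (2 above and 16 below of 23, camera adjusted p = 0.00119), hypoxia and glycolysis genes (1 above and 11 below of 15, camera adjusted p = 7.79e-04), ribosome biogenesis genes (0 above and 15 below of 16, camera adjusted p = 2.21e-06) and germline genes (0 above and 5 below of 6, camera adjusted p = 0.00163). With an estimated correlation the adjusted p-values were 0.204, 0.176, 0.133 and 0.176, in that order. Also passing in that direction was the list of housekeeping genes (0 above and 8 below of 12, camera adjusted p = 0.0185). It had an adjusted p = 0.245 with an estimated correlation. No other list passed in the interaction, except antigen presentation genes after quantile normalization (camera adjusted p = 0.0168). With median-of-ratios scaling the medians were 0.27 for developmental transcription factor genes (13 above and 2 below, as deposited 0.15) and 0.29 for p53 target genes (9 above and 1 below, as deposited 0.17). The medians after quantile normalization were 0.39 for developmental transcription factor genes (15 above and 3 below, as deposited 0.15), 0.40 for p53 target genes (11 above and 3 below, as deposited 0.17), 0.74 for Wnt pathway genes (5 above and 0 below, as deposited 0.51), -0.46 for hypoxia and glycolysis genes (1 above and 10 below, as deposited -0.71) and -0.27 for housekeeping genes (3 above and 6 below, as deposited -0.51). The camera call of housekeeping genes (adjusted p = 0.108) ended after quantile normalization. Adjusted over the list alone, the counts of the lists named here were the same, except 1 higher and 17 lower for homologous recombination repair, 0 higher and 71 lower for ribosomal protein genes, 0 higher and 14 lower for endoplasmic reticulum chaperones, 4 higher and 30 lower for androgen-induced genes, 11 higher and 3 lower for developmental transcription factor genes bound by PRC2, 4 higher and 1 lower for Wnt pathway genes, 1 higher and 13 lower for hypoxia and glycolysis, 1 higher and 8 lower for housekeeping genes.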

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

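The tests of library scaling and of the distribution of values between libraries were chosen after the results were seen. So were the median without kallikrein genes, the 3 patterns weighed and the values without a pseudocount. The results listed here were picked out because the effect of an agent differed with the other present, by the interaction test of limma. That reading presumes the single-agent doses in Combination, whose doses the labels do not give. Of 92 genes named here or in the report 78 departed from the sum of both single-agent changes, 56 below it and 22 above, with adjusted p-values up to 0.049, and 14 did not pass. Genes were named largely for extreme values in these data, so a high share was built in. Over all 11874 tested genes 39.6% departed.

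Interaction log2 changes below the sum were, among cell cycle and recombination genes, RRM2 -2.86, MKI67 -2.65, AURKB -2.23, CDC45 -2.1, CDC20 -2.0, BIRC5 -1.98, EXO1 -1.94, PLK1 -1.73, FEN1 -1.71, FANCI -1.62, MCM2 -1.53, KIF20A -1.49 and CCNA2 -1.35. Among androgen-regulated genes they were ALDH1A3 -1.7, NDRG1 -1.56, FKBP5 -1.46, LIFR -1.41, ACKR3 -1.33, SGK1 -1.2, CENPN -0.91, KLK3 -0.69, MPHOSPH9 -0.60, FOLH1 -0.58, STEAP2 -0.57, SLC45A3 -0.42 and TSC22D3 -0.36. Among other genes they were PIP -2.68, CYP4F8 -2.61, MYBL2 -2.61, SEMG2 -2.04, SCD -1.97, BCHE -1.92, SLC43A1 -1.87, FADS1 -1.8, LDHA -1.45, TFRC -1.37, ELOVL6 -1.32, BMPR1B -1.26, INSIG1 -1.14, GAPDH -1.13, HK2 -1.13, EZH2 -1.1, HSPA5 -1.06, MYC -1.06, ELOVL5 -0.97, PGC -0.96, FN1 -0.92, FBL -0.89, FASN -0.85, NCL -0.77, RPL14 -0.71, NOLC1 -0.58, XBP1 -0.46, B2M -0.31, COLEC12 -0.28 and RBBP7 -0.22. Above the sum were HOXC13 0.47, BARD1 0.52, HLA-B 0.52, MT1F 0.63, HLA-C 0.67, DPP4 0.69, HOXC4 0.82, WNT5A 0.90, ST6GALNAC1 0.99, COL1A1 1.03, SDC2 1.26, S100P 1.55, LEF1 1.71, COLCA1 2.13, LRRN1 2.42, TENM2 2.5, UPK2 2.56, UPK1A 2.67, IGFBP3 2.71, DAPK1 2.87, TNC 3.06 and ZFP36L2 3.12. The value depends on the pseudocount for genes low in a group. As ratios of mean FPKM with no pseudocount, which moved these by over 1.5 times, they were CYP4F8 -0.45, EXO1 -3.11, LRRN1 1.24, SLC45A3 -0.25, TENM2 1.2, TNC 0.62, UPK1A 0.92 and WNT5A 0.37, and the sign turned for PGC at 0.35 and UPK2 at -0.32. SEMG2 is listed at 0 in both DMSO libraries, so its departure rests on the pseudocount.

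Median-of-ratios scaling shifted interactions of all genes by a median of 0.12, so small departures below the sum are of the size of that shift. Of the 78 departing genes 75 still passed in the same direction with it, 53 below and 22 above, but not COLEC12 (-0.13), B2M (-0.17) and RBBP7 (-0.090). After quantile normalization 72 did, 50 below and 22 above, but not COLEC12 (0.13), SLC45A3 (-0.28), TSC22D3 (0.064), B2M (-0.015), RBBP7 (-0.033) and XBP1 (-0.18). The calls of SLC45A3 (-0.26), WNT5A (0.49) and PGC (-0.022) ended with a pseudocount of 0.1, and those of COLEC12 (-0.28) and RBBP7 (-0.22) with no filter. Leaving out a library, named with the value, ended the calls of COLEC12 (first DMSO -0.26, second DMSO -0.29, first ENZ -0.25, first EPZ -0.23, first Combination -0.22), SLC45A3 (second EPZ -0.38), B2M (first DMSO -0.28, second DMSO -0.33, second EPZ -0.23, first Combination -0.27) and RBBP7 (first DMSO -0.23, second DMSO -0.21, second ENZ -0.20, second EPZ -0.17, first Combination -0.21, second Combination -0.24). Values that still passed but moved by over 1.5 times were FASN -0.53, FN1 -0.51, FOLH1 -0.37, GAPDH -0.58, HLA-B 0.88, HLA-C 1.02, HOXC13 0.77, KLK3 -0.21, NCL -0.51, RPL14 -0.47, STEAP2 -0.34 and WNT5A 1.39 after quantile normalization, TSC22D3 -0.23 after median-of-ratios scaling and CYP4F8 -1.58, EXO1 -2.91, LRRN1 1.55, SEMG2 -3.86 and UPK2 1.54 with a pseudocount of 0.1.

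Cell cycle genes lay below the sum of both agents, with a median interaction of -1.54 over 62 genes of both lists. After median-of-ratios scaling the median was -1.44, after quantile normalization -1.72, and after a smooth trend on exonic length and expression was subtracted it was -1.39 (bootstrap SD 0.060, 0.0764 and 0.0745). Here and below the bootstrap resampled genes, so its SD ignores correlation between genes and does not measure the spread between libraries. Median-of-ratios scaling shifted all interactions by a median of 0.12, so it could not bring the cell cycle median near 0. It was therefore no test of scaling. The value after quantile normalization argues against the distribution of values between libraries as the whole cause. The value after subtraction argues against a length or expression trend as the whole cause. A candidate explanation left open is biological, that both agents together lowered the share of dividing cells by more than their separate effects add up to, but cell numbers and cycle phases were not measured. The adjusted p of this pattern is 0.0863 and 0.133 for the lists when the correlation is estimated.

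Ribosomal protein genes were lower in Combination by a median of -1.07, or -0.912 after median-of-ratios scaling. That scaling shifted all genes by a median of 0.16, so it could not have removed the fall. It presumes that most genes are unchanged, and a factor from the FPKM sums, which were also lower in Combination, was not tried. The share of summed FPKM in these genes, which no factor per library alters, was 11.7% and 11.6% in DMSO and 7.8% and 7.76% in Combination. Scaling as a part of the fall stays open. A difference in the distribution of values between libraries cannot be told apart: after quantile normalization the median was -0.387 (bootstrap SD 0.0345), between the bounds for and against. The 20 most abundant genes took a share of reads that differed by -0.865 percentage points between Combination and DMSO, so a few genes taking most of the reads is argued against. Gene length and abundance cannot be told apart either. Abundant genes of matched exonic length fell by a median of 0.778 themselves. Ribosomal protein genes differed from them at -0.291 (bootstrap SD 0.0601), between the bounds set in advance for and against. The matched genes were picked as abundant before they were matched on length, so their fall does not separate length from abundance. Log2 changes in Combination correlated with exonic length across genes (rho = 0.157). Lower ribosome production in Combination stays open and was not tested.

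Androgen-induced genes rose with EPZ and fell with ENZ. The EPZ median of 0.864 was 0.914 after median-of-ratios scaling and 0.909 after quantile normalization (bootstrap SD 0.182). Median-of-ratios scaling shifted all EPZ changes by a median of 0.050, so it could not bring the list median near 0 and was no test. The value after quantile normalization argues against the distribution of values between libraries as the whole cause. Without kallikrein genes the median was 0.852 (bootstrap SD 0.226), so the rise of the list did not rest on them alone. Leaving them out kept 39 of 42 members and could hardly move a median, so it was no test of shared reads. A biological effect of EPZ on androgen-regulated genes is a hypothesis these values leave open.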

How the results depend on the processing

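Gene list tests under both scalings and values with no pseudocount were chosen after the data were seen. Every total of changed genes stayed within 1.5 times under all alternatives, but counts by direction and of 2-fold changes did not. Leaving out each library in turn, where the lone library of a group is assumed to vary like the others, gave 5265 to 6582 for ENZ, 4899 to 7218 for EPZ, 8923 to 9814 for Combination, 7425 to 8259 for Combination against ENZ, 7556 to 9051 for Combination against EPZ and 3395 to 5272 for the interaction. With the replicate number as a block the counts were 6914, 6783, 9657, 8515, 8783 and 4942 in that order. With only the compared groups in the fit they were 6011 for ENZ and 7268 for EPZ, against 6733 and 6623. The labels do not say whether same-numbered libraries were handled together. Their deviations correlated at -0.0153 to 0.109, so any effect they share was small, and the numbers were not treated as pairs. The block ended the call of 1 list, hypoxia and glycolysis genes in Combination (adjusted p = 0.0533). The correlation of ENZ effects with and without EPZ was 0.76 with a pseudocount of 0.1, 0.736 with no filter, 0.795 at a mean of at least 5 FPKM and 0.72 after quantile normalization, and that of EPZ effects 0.722, 0.705, 0.78 and 0.702. The cause was not tested. Some genes called both as deposited and after quantile normalization had opposite signs. They numbered 277 of 8219 in Combination, 88 of 6968 against ENZ and 137 of 7366 against EPZ. With ENZ they numbered 4, with EPZ 0 and in the interaction 2. Of 4703 interaction calls 3647 were also called after median-of-ratios scaling and 3677 after quantile normalization. Of 3314 values of named genes under an alternative, 3266 kept direction and side of the threshold, 8 came to pass it, 31 ceased to pass it, and 14 changed sign, of which 5 also crossed it. The lost calls were all interactions except CDKN1A in Combination against EPZ. After quantile normalization the sign changed for CDKN1A in Combination against EPZ at 0.0823, TMPRSS2 in Combination at 0.619 (0.113 after median-of-ratios scaling), EZH2 with ENZ at 0.049, and the interactions of COLEC12 at 0.127 and TSC22D3 at 0.0642. Without a library EZH2 with ENZ ranged over -0.133 to 0.0247, above 0 without the first ENZ library, and interactions without a library ranged over -0.0403 to 0.112 for KLK2 and -0.0277 to 0.0286 for TMPRSS2. Without a pseudocount the interactions of PGC and UPK2 became 0.353 and -0.319. List tests changed direction after quantile normalization with adjusted p-values of 0.13 for endoplasmic reticulum chaperones with ENZ, 0.455 for developmental transcription factor genes bound by PRC2, 0.715 for interferon response and 0.275 for cholesterol synthesis and uptake with EPZ, 0.661 for luminal prostate markers and 0.0431 for endoplasmic reticulum chaperones in Combination, 0.21 for endoplasmic reticulum chaperones against ENZ and 0.441 for EZH2-repressed tumour genes and 0.833 for luminal prostate markers in the interaction. After median-of-ratios scaling they did so with 0.969 for cholesterol synthesis and uptake with EPZ and 0.916 for PRC2 subunits and 0.805 for EZH2-repressed tumour genes in the interaction. The cause of these was not tested. Camera calls lost with an estimated correlation numbered 14 for ENZ, 13 for EPZ, 14 for Combination, 16 for Combination against ENZ, 16 for Combination against EPZ and 15 for the interaction. Depth limits the genes near the filter, where few fragments lie behind a value.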

Other observations

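These families were chosen by gene symbol after their values were seen, and the test of silent developmental genes was chosen after the results were seen. In Combination 77 of 78 mitochondrial ribosomal protein genes fell, with a median of -1.19, as did 35 of 35 proteasome subunit genes (-1.06), 36 of 37 subunits of respiratory complex I (-0.87) and all 11 spliceosomal Sm and snRNP protein genes (-1.58). After quantile normalization these medians were -0.84 (0 higher and 73 lower), -0.52 (1 and 30), -0.38 (3 and 28) and -1.29 (0 and 11). As deposited, 290 abundant genes matched on exonic length to ribosomal protein genes had a median of -0.778 in Combination. These families were not set against a matched background of their own. Falls near that value cannot be told apart from a general fall of abundant genes. Collagens rose in 10 of 12 (1.5) and semaphorins in 11 of 12 (1.09). With EPZ, 22 of 33 histone genes rose and 2 fell (0.61) while all 32 measured members of the G1/S and DNA replication list fell. Replication-dependent histone transcripts lack a poly(A) tail, and how the RNA was selected is not known here.

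Genes under 0.1 FPKM in both DMSO libraries that reached at least 1 FPKM in both treated libraries numbered 12 with ENZ, 15 with EPZ and 108 in Combination, of which 2, 6 and 63 are protein-coding. The reverse held for 4, 1 and 8. In Combination the uroplakin genes UPK2 and UPK1A, of the urothelial surface, reached 18.6 ± 1.26 and 12.1 ± 1.52 FPKM, the teneurin gene TENM2 13.4 ± 1.2, TNC 12.2 ± 0.105 and DAPK1 9.71 ± 0.482 (n = 2). With EPZ alone SEMG2, a semenogelin gene that shares reads with its close copy, reached 4.31 ± 0.248 FPKM, and it stood at 0.36 in Combination. These genes were named after their values were seen.

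A hypothesis was that EPZ released silent PRC2-bound developmental genes. Of 36 such list members under the expression filter with a value above 0, 33.3% had both EPZ values above both DMSO values. The share was 30.5% of 688 other genes matched on mean FPKM. The difference of 2.81 percentage points does not decide with so few genes. Both the filter and the matching used the mean over all libraries, treated ones included. Genes raised strongly could thus leave the set, and the matching itself depends on the rise. The shares were 52.8% and 48.1% in Combination, and 22.2% and 25.7% with ENZ, where members lay below the matched genes.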
